A study of Mus musculus with 60 samples.

How the data were processed

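RNA was measured by sequencing in 60 libraries of NMuMG and 4T1 cells, and the deposited values are counts of reads per gene, per the file headers. NMuMG cells were grown in 6-well plates and their libraries were made, sequenced and processed by a sequencing company, per the labels' protocols. Libraries of 4T1 were made with a stranded mRNA kit and sequenced as read pairs, per the labels' protocols. The submitters' processing notes name Trim Galore 0.6.7, STAR 2.7.10a, HISAT2, DESeq2 and edgeR and the mm10 genome without a role or order for each. Which aligner made which table is not given in the sources used here. Gene symbols, identifiers and coordinates were taken as the count tables give them, and the coordinates are those of GRCm38 (mm10). Each experiment was analysed alone, since each has a table of its own.

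All 60 libraries and all columns of counts were used, in 20 groups of 3. The tables list 54532 genes for each NMuMG experiment and 55487 for 4T1. Genes with too few counts were left out with edgeR's filterByExpr (minimum count 10, minimum total count 15), which kept 14345, 14983 and 13854 genes in experiments 1, 2 and 3. Library totals were 16.2 to 21.9 M, 15.6 to 22.7 M and 22 to 31.1 M, and TMM factors 0.941 to 1.08, 0.954 to 1.09 and 0.973 to 1.03. The biological coefficient of variation was 2.88%, 7.59% and 2.95%.

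Groups were compared with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood test with 1 coefficient per group and all groups of an experiment in 1 fit. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes tested in a comparison, and the threshold was 0.05. An exact test of 3 against 3 libraries cannot go below 0.10, which is why a model across all genes was used. TGFβ1 times were compared with 0 h (or 0 d), genotypes at each time, and the interaction is the TGFβ1 change in the altered cells minus that in control. A second count takes genes that also changed at least 2-fold. For genes with 0 counts in a group, folds were computed against a floor of 3 counts over the group, and for 1 to 3 counts the ratio is given with its 95% counting interval.

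Gene lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, and again with a correlation estimated from the data. Their p-values were adjusted over all lists and the 4 main comparisons of an experiment. The 25 lists were epithelial adhesion and polarity, mesenchymal markers, EMT transcription factors, TGFβ and SMAD targets, extracellular matrix, actin and SRF targets, interferon response, MHC class I presentation, inflammatory and NF-κB targets, AP-1 and immediate early genes, ATF4 and integrated stress response, p53 targets, hypoxia and glycolysis, cholesterol synthesis, NRF2 targets, G2/M and mitosis, DNA replication and S phase, SWI/SNF subunits, YAP and TEAD targets, mitochondrially encoded mRNAs, and markers of fibroblasts, leukocytes, endothelium, basal and luminal mammary cells. A pair of further lists took the 200 genes with the smallest p among those induced, or repressed, at least 2-fold at 72 h in control cells of the other NMuMG experiment (of experiment 2 for 4T1). Their interaction p-values were adjusted over the 6 results. The G2/M list in experiment 1 and the interferon list in experiment 2 were also tested between genotypes at every time, chosen after their levels were seen, with p-values adjusted over these 14 results. Replicates of a group were compared pair by pair with a chi-square test of their counts. Overlaps were set against the number expected from independent lists.

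The genes named were set by a rule. It takes Pbrm1 and Atf3, 11 EMT and TGFβ genes (Cdh1, Epcam, Cdh2, Vim, Fn1, Acta2, Zeb1, Snai1, Snai2, Smad7 and 1 that is not reported here), the 8 genes per direction with the largest changes at 10 CPM or more in the higher group whose libraries do not overlap, and at most 4 passing members per list. With 3 libraries against 3, chance alone keeps groups from overlapping in 10% of genes. The text names a part of these, larger changes first. The genes shared between the PBRM1 experiments were named after their values were seen. The comparisons, lists, rule and alternatives were set before the data were examined, except where a choice is said to have been made later.

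The tests were tried on simulated counts with known changes, drawn from the real means and library sizes. At 2-fold, edgeR found 84%, 68% and 96% of 50 changed genes in the genotype comparisons without TGFβ1 of experiments 1, 2 and 3 (13853, 14521 and 13603 genes run), and 70%, 60% and 86% in the interactions at the last time. Unchanged genes were called in 0.102%, 0.0628% and 0.097%. Each simulated gene had 1 mean over all groups, and few genes were changed. In the real comparisons without TGFβ1, 45.1%, 37% and 51% of genes passed, which loosens the cut-off of the adjustment. The simulated shares found and falsely called therefore do not carry over to the real comparisons.

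Alternatives were RLE factors, library totals alone, no filter on low counts, at least 1 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, fits with only the groups compared, the replicate number as a block, leaving out each library, fry in place of camera, TGFβ lists of 100 or 500 genes, and overlaps at 2-fold. The labels do not say that a replicate number pairs libraries across groups, and no block is in the reported values. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.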

Results

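RNA sequencing counts were examined for 60 libraries of 2 mouse cell lines, in 20 groups of 3 libraries that the labels call biological replicates. NMuMG is a mouse mammary gland epithelial line that undergoes an epithelial to mesenchymal transition (EMT) under TGFβ, and 4T1 is a mouse mammary carcinoma line. Experiment 1 compared NMuMG cells labelled sgCT (control) and sgPBRM1 (PBRM1 knockout) after 0, 24, 48 and 72 h of TGFβ1 at 5 ng/ml. PBRM1 is the polybromo subunit of the PBAF form of the SWI/SNF chromatin remodelling complex. Experiment 2 compared NMuMG cells labelled pLKO (control) and shATF3 (ATF3 knockdown) over the same times. ATF3 is a stress-induced transcription factor of the ATF/CREB family. Experiment 3 compared 4T1 cells labelled pLKO (control) and shPBRM1 (PBRM1 knockdown) at 0 and 4 d of TGFβ1. Total counts per library were 16.2 to 21.9 M in experiment 1, 15.6 to 22.7 M in experiment 2 and 22 to 31.1 M in experiment 3. The p-values measure the spread between the 3 cultures of a group as labelled, within 1 cell population per genotype as far as the labels tell. Levels are counts scaled to a common library size with TMM factors (CPM), given as mean and SD over n = 3 libraries. Fold changes are log2 values with their standard error (SE) and adjusted p from edgeR, and coordinates are GRCm38.

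The targeted genes were examined in every group first. Pbrm1 (ENSMUSG00000042323, chromosome 14, 31019138 to 31121592) was only slightly lower in the knockout libraries of experiment 1. It stood at 115 CPM (SD 0.37) in control and 97.2 CPM (SD 3.37) in knockout at 0 h (log2 fold change −0.25, SE 0.0403, adjusted p = 6.82e-07). At 72 h the levels were 101 CPM (SD 1.41) and 89.0 CPM (SD 6.56). A knockout made with a guide RNA can leave the mRNA in place, so this level checks the labels little. In 4T1 the knockdown lowered Pbrm1 from 236 CPM (SD 3.2) to 28.3 CPM (SD 1.78) at 0 d (log2 fold change −3.05, SE 0.0423). At 4 d it lowered Pbrm1 from 223 CPM (SD 3.26) to 31.1 CPM (SD 2.55).

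Atf3 (ENSMUSG00000026628, chromosome 1, 191170296 to 191218039) went against its label at 0 h in experiment 2. It stood at 9.95 CPM (SD 0.82) in control and at 12.3 CPM (SD 1.44) in the libraries labelled ATF3 knockdown (log2 fold change 0.31, SE 0.148, adjusted p = 0.106). It was lower in them at 24 h (−0.59, SE 0.138, adjusted p = 0.00135) and 72 h (−0.46, SE 0.163, adjusted p = 0.0326), and its value at 48 h was −0.38 (adjusted p = 0.0575), which passed without a filter on low counts (0.0322), with DESeq2 (0.04) and with only the groups compared (0.0103). The 72 h difference did not pass with only the groups compared (−0.47, adjusted p = 0.181) or without replicate 2 (−0.25, 0.248) or 3 (−0.39, 0.122) of the libraries labelled ATF3 knockdown or replicate 1 (−0.44, 0.086) or 2 (−0.43, 0.0867) of control. The shATF3 libraries are therefore called the libraries labelled ATF3 knockdown, and no direction drawn from them assumes that ATF3 was reduced before TGFβ1. In experiment 1, Atf3 was lower in PBRM1 knockout at every time, with 5.45 CPM (SD 0.976) against 11.8 CPM (SD 0.398) at 0 h. At 72 h it stood at 6.45 CPM (SD 0.327) against 30.9 CPM (SD 1.26), a log2 fold change of −2.26 (SE 0.0893, adjusted p = 2.41e-30). TGFβ1 raised Atf3 in control by 1.73 at 24 h and by 1.39 at 72 h (log2 scale). The 72 h response was smaller in knockout by −1.15 (SE 0.143, adjusted p = 1.38e-09), whereas the differences at 24 h (−0.12, adjusted p = 0.586) and 48 h (−0.19, adjusted p = 0.332) did not pass.

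**Figure D1:**
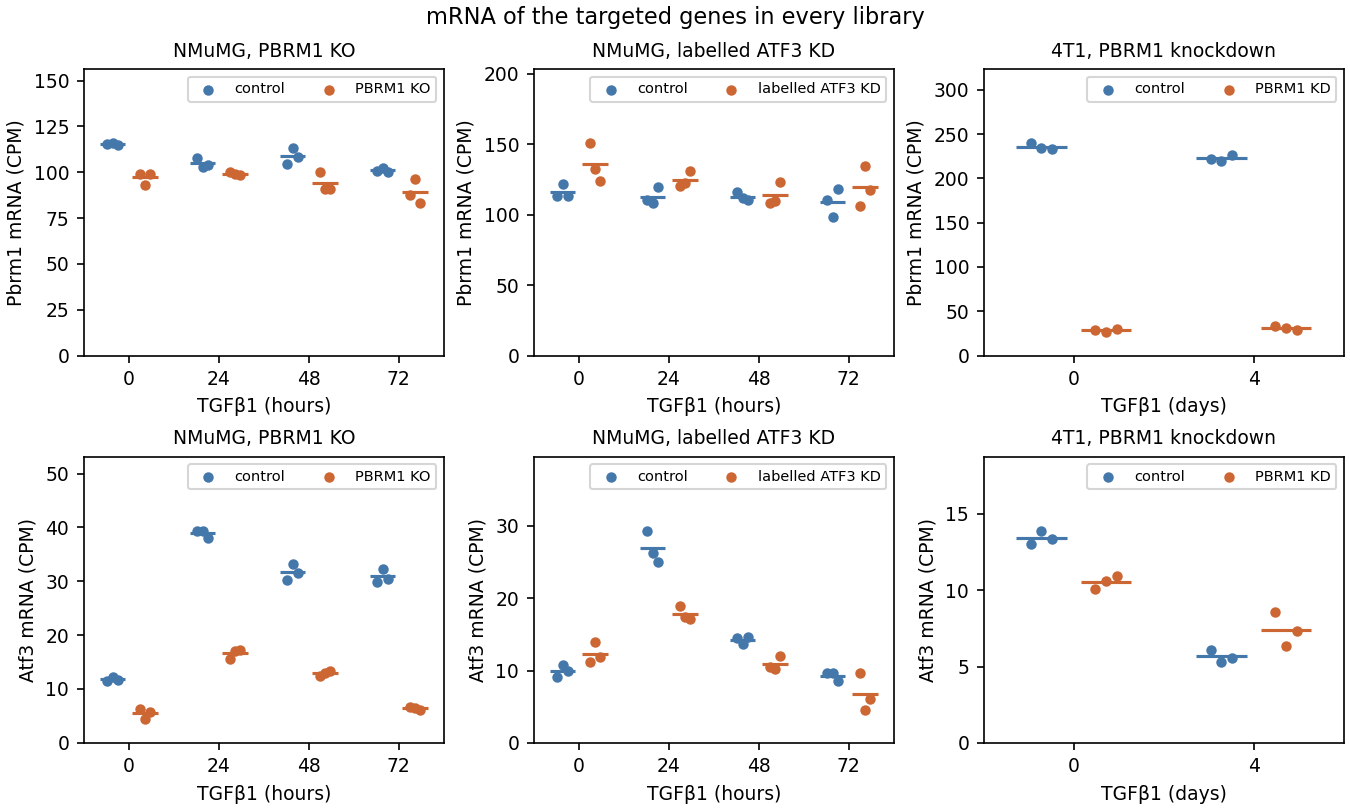
Pbrm1 and Atf3 in each library, in CPM, by group and time of TGFβ1, with each point a library and each horizontal line the mean of n = 3. Pbrm1 falls from 236 to 28.3 CPM with the 4T1 knockdown but only from 115 to 97.2 CPM in the NMuMG knockout at 0 h, and Atf3 at 0 h of experiment 2 is 9.95 CPM in control and 12.3 CPM in the libraries labelled ATF3 knockdown.

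The first question was how control NMuMG cells respond to TGFβ1. After 72 h in experiment 1, E-cadherin (Cdh1, ENSMUSG00000000303, chromosome 8, 106603351 to 106670246), the adherens junction cadherin of epithelia, fell from 828 CPM (SD 17.9) to 380.5 CPM (SD 8.65; log2 fold change −1.12, SE 0.0287, adjusted p = 5.1e-41). Fibronectin (Fn1, ENSMUSG00000026193, chromosome 1, 71585520 to 71653200) rose from 683 CPM (SD 34.1) to 8164 CPM (SD 486; 3.58, SE 0.0324). Smooth muscle actin (Acta2, ENSMUSG00000035783, chromosome 19, 34241090 to 34255336) rose from 0.0900 CPM (SD 0.113) to 24.3 CPM (SD 1.37; adjusted p = 1.94e-38). Collagen I (Col1a1) rose from 2.55 CPM (SD 0.202) to 756 CPM (SD 32.9; 8.21, SE 0.0648). The EMT transcription factors Snai1 (3.54, SE 0.138), Zeb2 (2.62, SE 0.059) and Zeb1 (1.77, SE 0.045) rose as well, with a smaller rise of Snai2 (0.42, SE 0.166, adjusted p = 0.0216) that did not pass with library totals alone (0.30, 0.1), without replicate 1 at 0 h (0.27, 0.178) or without replicate 1 (0.38, 0.0722) or 3 (0.32, 0.132) at 72 h. N-cadherin (Cdh2) rose by 1.10 (SE 0.0343), vimentin (Vim) was already at 1845 CPM (SD 41.8) and gave −0.00 (adjusted p = 0.894, or −0.12 and 3.3e-06 with library totals alone), and Epcam stood at 0.447 CPM or less.

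The genes with the largest rises included Lrrc32, which encodes GARP, a surface receptor for latent TGFβ (10.30, SE 0.101, 208 CPM at 72 h), argininosuccinate synthase Ass1 (10.12, SE 0.134) and hyaluronan synthase Has2 (8.38, SE 0.208). Col5a3 and Mmp9 had 1 and 2 counts over the 0 h libraries, and their ratios were 8260 (95% counting interval 1480 to 326000) and 1530 (424 to 12700). The largest falls included the RhoGAP gene Arhgap40 (−7.49, SE 0.187), the deiodinase gene Dio3 (−8.04, SE 0.241), the galectin Lgals4 (−6.76, SE 0.108) and the antitrypsin gene Serpina1b (−6.79, SE 0.112). Reads of Serpina1b may be shared with its near-identical paralogs, and those of Dio3 with its antisense neighbour Dio3os, so both values are uncertain. Such intervals, and the bounds given for genes at 0 counts, cover counting error only.

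At 72 h, 9944 of 14345 tested genes passed at adjusted p under 0.05, 5007 higher and 4937 lower, and 3235 of them moved at least 2-fold. The counts were 8524 at 24 h and 9390 at 48 h, with 1932 and 2703 genes at least 2-fold. Scaling by library totals alone put the median of all genes at 72 h at −0.119 in place of 0.000669 and lowered the share of higher genes among those passing from 50.4% to 40.2%. At 24 h the share went from 50.4% to 40.1%. The 10 most abundant genes held 4.82% of counts (SD 0.0173) at 0 h and 6.23% (SD 0.07) at 72 h. No NMuMG group is labelled with a later time without TGFβ1, so time in culture and TGFβ1 are not separated.

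Gene lists written down before the data were examined described this response in control cells at 72 h. Of 29 tested epithelial adhesion and polarity genes, 24 fell and 5 rose (median −1.12, camera adjusted p = 5.94e-06). Among those that rose was the tight junction gene Cldn4 (6.95, SE 0.177). Among mesenchymal markers 17 of 21 rose and 2 fell (adjusted p = 7.81e-10), and among actin cytoskeleton and SRF targets all 20 rose (median 1.46, adjusted p = 2.65e-16). TGFβ and SMAD targets rose in 26 of 31 and fell in 5 (adjusted p = 5.63e-10), with thrombospondin 1 (Thbs1, 6.16, SE 0.0298) and the inhibitory SMAD Smad7 (1.43, SE 0.043) as examples. Extracellular matrix genes rose in 29 of 38 and fell in 6 (7 adjusted over the list alone; adjusted p = 2.39e-08), with a median of 1.71, or 1.48 with genes at few counts set to their bound. All 28 G2/M and mitosis genes fell (median −1.64, adjusted p = 1.3e-22), as did all 30 DNA replication and S phase genes (median −1.57, adjusted p = 7.22e-21), with Kif11 (−2.11, SE 0.043) and Uhrf1 (−2.56, SE 0.0402) as examples. Cholesterol synthesis genes fell in 22 of 24 (median −0.62, adjusted p = 5.26e-08), among them Hmgcs1 (−1.23, SE 0.0354). NRF2 targets fell in 18 of 23 and rose in 5 (adjusted p = 0.000153), with the glutathione synthesis gene Gclc at −2.45 (SE 0.0417) and heme oxygenase Hmox1 at 2.44 (SE 0.0489). Targets of p53 fell in 17 of 25 and rose in 5 (18 fell, adjusted over the list alone; adjusted p = 0.00512). These lists also passed with an estimated correlation between genes, and apart from the 2 named their counts adjusted over the list alone were the same.

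Other lists passed only at the preset correlation in the same comparison. EMT transcription factors rose in 9 of 11 (adjusted p = 0.00188; adjusted p = 0.0593 with an estimated correlation). Inflammatory and NF-κB targets rose in 14 of 24 and fell in 6 (0.00422; adjusted p = 0.0795 with an estimated correlation). AP-1 and immediate early genes rose in 17 of 26 and fell in 6 (0.00262; adjusted p = 0.269 with an estimated correlation), with Jun at 3.27 (SE 0.0562). YAP and TEAD targets rose in 14 of 19 and fell in 5 (0.00104; adjusted p = 0.222 with an estimated correlation), among them Ctgf (2.62, SE 0.0269) and Cyr61 (2.75, SE 0.0341). MHC class I presentation genes rose in 10 of 16 and fell in 2 (3 adjusted over the list alone; 0.0389; adjusted p = 0.176 with an estimated correlation), with B2m at 1.54 (SE 0.0309). The lists that did not pass were interferon response (10 rose, or 12 adjusted over the list alone, and 11 fell of 29, adjusted p = 0.912, median 0.06 but mean −0.29), ATF4 and integrated stress response (12 and 14 of 30, 0.722), hypoxia and glycolysis (15 and 11 of 33, 0.411), SWI/SNF subunits (12 and 7, or 8 adjusted over the list alone, of 25, 0.599) and mitochondrially encoded mRNAs (5 and 3 of 13, 0.994, median 0.07 but mean −0.05). Cell type markers gave fibroblast 3 and 1 of 5 (0.162), leukocyte 3 and 0 of 3 (0.285), endothelial 0 and 1 of 2 (0.722), basal and myoepithelial 3 and 0 of 4 (0.155) and luminal mammary 3 and 5 of 8 (0.545).

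The PBRM1 comparison at 0 h asked what differs before TGFβ1. Knockout cells had less of the imprinted zinc finger gene Peg3 (ENSMUSG00000002265, chromosome 7, 6703892 to 6730431), with 12.6 CPM (SD 1.14) against 258 CPM (SD 6.33) in control (log2 fold change −4.36, SE 0.0522, adjusted p = 2.95e-57). The simple epithelial keratin Krt7 (ENSMUSG00000023039, chromosome 15, 101411043 to 101430313) stood at 69.8 CPM (SD 3.41) against 785 CPM (SD 13.7; −3.49, SE 0.0337). The water channel Aqp1 (−4.13, SE 0.177) and the RhoGAP Dlc1 (−3.19, SE 0.136) were lower too. Higher in knockout were the zinc finger gene Cxxc5 (3.49, SE 0.142), the cytochrome P450 Cyp1b1 (3.21, SE 0.121), the proteoglycan Sdc3 (2.02, SE 0.0807) and collagen VI (Col6a2, 1.86, SE 0.0631). Fn1 stood at 1230 CPM (SD 25.9) against 683 CPM (SD 34.1; 0.85, SE 0.0302), Snai1 stood at 4.56 CPM (SD 0.492) against 1.60 CPM (SD 0.315), and Zeb2 (1.03, SE 0.0692) was higher as well. Cdh1 was also higher (0.23, SE 0.0274, adjusted p = 2.88e-10). In all, 6474 genes passed, 3143 higher and 3331 lower in knockout, and 736 differed at least 2-fold. Among those passing 48.5% were higher, or 55.2% with library totals alone.

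At 0 h the cholesterol synthesis genes were lower in knockout in 21 of 24 (22 adjusted over the list alone; median −0.49, camera adjusted p = 1.36e-15), with Insig1 at −0.83 (SE 0.0529) and Hmgcs1 at −0.79 (SE 0.0337). DNA replication genes were lower in 26 of 30 (median −0.35, adjusted p = 7.39e-16), with Mcm3 at −0.60 (SE 0.032). Targets of p53 were lower in 17 of 25 and higher in 3 (adjusted p = 0.000149), among them Gdf15 (−1.79, SE 0.203). Epithelial genes were lower in 17 of 29 and higher in 4 (adjusted p = 6.42e-06), against the direction of Cdh1. These 4 lists passed with an estimated correlation. Hypoxia and glycolysis genes were higher in 22 of 33 (23 adjusted over the list alone) and lower in 2 (2.39e-08; adjusted p = 0.266 with an estimated correlation), with Bnip3 at 0.97 (SE 0.0703) and Pdk1 at 0.66 (SE 0.0525). G2/M genes were lower in 19 of 28 and higher in 1 (2.01e-06; adjusted p = 0.0989 with an estimated correlation, or 0.0403 adjusted over the 14 results of the lists tested at every time), and matrix genes higher in 17 of 38 and lower in 7 (0.000278; adjusted p = 0.156 with an estimated correlation). Mesenchymal markers were higher in 10 of 21 and lower in 5 (0.0098; adjusted p = 0.295 with an estimated correlation), where the median was 0.14 and the mean −0.35. YAP and TEAD targets were lower in 13 of 19 (14 adjusted over the list alone) and higher in 4 (0.00422; adjusted p = 0.278 with an estimated correlation), with Ankrd1 at −0.74 (SE 0.0325) and Cyr61 at −0.58 (SE 0.0381). Counts given once were the same adjusted over the list alone.

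After 72 h of TGFβ1, knockout cells had 68.7 CPM (SD 0.498) of the proliferation marker Mki67 against 217 CPM (SD 2.75) in control (log2 fold change −1.66, SE 0.0367, adjusted p = 8.85e-43). Peg3 (−5.59, SE 0.0587) and Krt7 (−3.64, SE 0.0393) stayed lower, and complement C3 stood at 2.22 CPM (SD 0.419) against 36.8 CPM (SD 3.15; −4.04, SE 0.11). The growth factor Fgf2 stood at 31.5 CPM (SD 2.89) against 2.31 CPM (SD 0.316; 3.77, SE 0.147), and carbonic anhydrase Car12 (2.75, SE 0.101), the EGF family ligand Btc (2.43, SE 0.142) and Tgfb3 (1.63, SE 0.131) were higher. Acta2 stood at 48.5 CPM (SD 3.56) against 24.3 CPM (SD 1.37; 1.00, SE 0.0807), and Snai2 (0.85, SE 0.146), Snai1 (0.79, SE 0.081), Fn1 (0.54, SE 0.0289) and Cdh1 (0.26, SE 0.0292) were higher too. Vim did not differ past the test (−0.04, adjusted p = 0.24, or −0.08 and 0.00366 with library totals alone). In all, 7161 genes passed, 3490 higher and 3671 lower, and 1176 at least 2-fold. The counts were 6709 at 24 h and 7177 at 48 h. The share of higher genes was 48.7% at 72 h and 48.8% at 48 h, or 40.3% at both times with library totals alone.

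All 28 G2/M genes were lower in knockout at 72 h (median −1.46, camera adjusted p = 2.5e-33), among them Birc5 (−1.73, SE 0.0786), and 29 of 30 replication genes were lower (median −0.94, adjusted p = 1.97e-21), with Tk1 at −1.48 (SE 0.0746). Epithelial genes were lower in 20 of 29 and higher in 2 (adjusted p = 8.81e-09), with the mucin Muc1 (−2.27, SE 0.262) and Cldn4 (−2.15, SE 0.0965) as examples. TGFβ and SMAD targets were higher in 20 of 31 and lower in 1 (adjusted p = 7.63e-09), with the CDK inhibitor Cdkn2b at 0.78 (SE 0.0371). These 4 lists passed with an estimated correlation and had the same counts adjusted over the list alone. Hypoxia genes were higher in 28 of 33 (29 adjusted over the list alone) and lower in 2 (2.42e-13; adjusted p = 0.132 with an estimated correlation), with the enolase Eno2 at 1.62 (SE 0.12). Mesenchymal markers were higher in 15 of 21 and lower in 5 (2.86e-06; adjusted p = 0.0666 with an estimated correlation), among them Nt5e (1.48, SE 0.0345). Inflammatory genes were lower in 12 of 24 and higher in 8 (0.0322; adjusted p = 0.183 with an estimated correlation), with the chemokine Ccl2 at −2.38 (SE 0.0538). At 72 h the 10 most abundant genes held 7.66% of counts (SD 0.114) in knockout and 6.23% (SD 0.07) in control.

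Whether knockout changed the TGFβ1 response was tested as the interaction at 72 h, the change from 0 h in knockout minus that in control. Mitotic genes fell further in knockout by 72 h, with Ccnb2 (interaction −1.76, SE 0.0786, adjusted p = 7.61e-27), Kif2c (−1.71, SE 0.101) and Birc5 (−1.55, SE 0.091) as examples. Cholesterol synthesis genes moved the other way, with Hmgcs1 at 1.01 (SE 0.0504), Insig1 at 1.30 (SE 0.0769) and Fdps at 1.38 (SE 0.183). Dlc1 (4.30, SE 0.144), the scavenger receptor Olr1 (3.19, SE 0.128), Fgf2 (3.09, SE 0.302) and the transcription factor Maf (2.84, SE 0.139) responded more upwards, and C3 (−4.29, SE 0.132) and the steroid hydroxylase Cyp21a1 (−3.25, SE 0.143) more downwards. Of the EMT genes, Col1a1 (−1.50, SE 0.153), Snai1 (−0.71, SE 0.201, adjusted p = 0.00463, or −0.57 and 0.0517 without control replicate 1 at 0 h) and Fn1 (−0.31, SE 0.0416) rose less and Snai2 (0.96, SE 0.226) and Cdh2 (0.20, SE 0.0485) rose more. The responses of Cdh1 (0.03, adjusted p = 0.647), Zeb1 (0.15, adjusted p = 0.0699, or 0.18 and 0.0474 without control replicate 3 at 0 h) and Acta2 (0.79, adjusted p = 0.602) did not differ past the test. The interaction passed for 3937 genes, 1671 higher and 2266 lower, after 2637 at 24 h and 3484 at 48 h, and 609 exceeded 2-fold at 72 h. With library totals alone the share of higher genes went from 42.4% to 26.1% at 72 h, from 44.4% to 25.4% at 48 h and from 46.3% to 35.6% at 24 h. The TGFβ1 response within knockout itself passed for 10194 genes, 50.9% of them higher, or 36.0% with library totals alone, which put its all-gene median at −0.188 in place of 0.00104.

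In the 72 h interaction all 28 G2/M genes were lower (median −1.28, camera adjusted p = 9.87e-52). The list moved the other way in the 24 h interaction, with 27 of 28 higher and 0 lower (median 0.37; adjusted p = 0.000135 with an estimated correlation), and in that at 48 h all 28 were lower (median −0.79; adjusted p = 3.12e-05 with an estimated correlation). Relative to untreated control, its medians per library at 24 h were −0.416 to −0.366 in knockout and −0.555 to −0.505 in control, after −0.215 to −0.188 in knockout at 0 h. These tests at 24 and 48 h were added after the levels were seen, and their counts were the same adjusted over the list alone. Replication genes were lower in 25 of 30 in the 72 h interaction (26 adjusted over the list alone) and higher in 1 (median −0.58, adjusted p = 8.64e-19), with Mcm10 at −1.21 (SE 0.114) and Pole at −1.19 (SE 0.0794). Cholesterol synthesis genes were higher in 20 of 24 and lower in 1 (median 0.56, adjusted p = 1.53e-21). Their medians in knockout libraries, relative to untreated control, were −0.512 to −0.426 at 0 h and −0.568 to −0.506 at 72 h. Against control at 72 h they were higher in 11 and lower in 1 (median 0.06, adjusted p = 0.0487, or 0.0536 with the replicate block; adjusted p = 0.266 with an estimated correlation). Epithelial genes were lower in 15 of 29 and higher in 1 (adjusted p = 0.000239), among them the tight junction gene Cgn (−1.16, SE 0.069) and the epithelial transcription factor Ehf (−1.69, SE 0.253). In the 72 h interaction these 4 lists passed with an estimated correlation. Inflammatory genes were lower in 12 of 24 (15 adjusted over the list alone) and higher in 4 (0.00131; adjusted p = 0.0608 with an estimated correlation), with Ccl7 at −1.97 (SE 0.275). TGFβ and SMAD targets were higher in 15 of 31 (17 adjusted over the list alone) and lower in 6 (7 adjusted over the list alone; 0.00071; adjusted p = 0.124 with an estimated correlation). Matrix genes did not pass (10 higher and 9 lower of 38, or 11 and 10 adjusted over the list alone, 0.71), with a median of −0.09 and a mean of 0.15.

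The response was also read with lists taken from the other NMuMG experiment, the 200 genes that TGFβ1 induced and the 200 that it repressed most clearly in control at 72 h of experiment 2. All 200 induced genes rose in control cells of experiment 1 at 72 h and 196 of the repressed genes fell. In knockout against control at 72 h, 153 induced genes were higher and 26 lower (median 0.33), and 158 repressed genes were lower and 16 higher (median −0.61). The interaction at 72 h gave a median of 0.10 for the induced list, with 83 higher and 46 lower (adjusted p = 1.85e-07 over the interactions at the last time; adjusted p = 0.0532 with an estimated correlation, or 0.0446 adjusted over all comparisons of these lists). At 24 and 48 h the induced list gave medians of 0.15 (92 higher and 25 lower) and 0.25 (104 and 29), with adjusted p = 0.00531 and 0.00196 with an estimated correlation. At 72 h the interaction gave −0.49 for the repressed list, with 136 lower and 22 higher (adjusted p = 4.18e-30; 8.37e-08 with an estimated correlation).

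**Figure D2:**
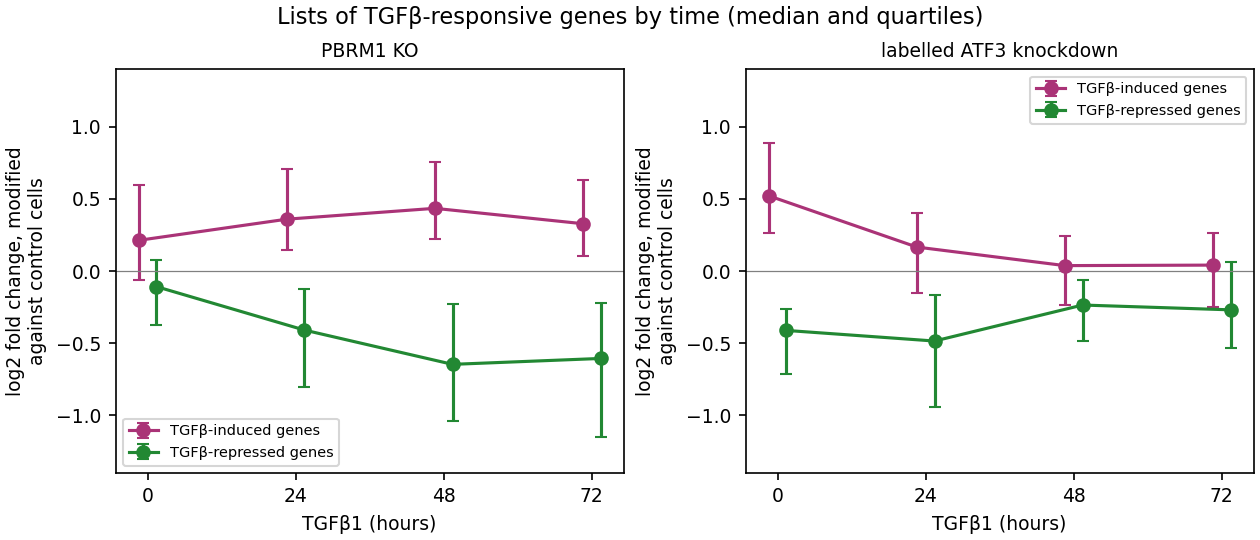
Median log2 fold change of the TGFβ-induced and TGFβ-repressed lists (vertical axis, log2) in genotype comparisons by time of TGFβ1, with bars from the lower to the upper quartile of the listed genes. In experiment 1 the repressed list goes from −0.11 at 0 h to −0.61 at 72 h in knockout against control, and in experiment 2 the induced list goes from 0.52 at 0 h to 0.04 at 72 h in the libraries labelled ATF3 knockdown.

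Control cells of experiment 2 were an independent look at the same treatment. After 72 h Cdh1 fell from 599 CPM (SD 23) to 108 CPM (SD 6.78; log2 fold change −2.47, SE 0.0738, adjusted p = 5.36e-21), and Fn1 (3.30, SE 0.0573), Acta2 (6.94, SE 0.19), Col1a1 (7.27, SE 0.168), Snai1 (3.69, SE 0.115) and Zeb1 (1.55, SE 0.0769) rose. Ass1 rose by 9.63 (SE 0.183), and the secreted protein gene Srpx2, with 0 counts over the 0 h libraries, was at least 610-fold higher. The inhibitor of differentiation Id2 fell by 3.75 (SE 0.0672), and complement C3 (−5.21, SE 0.22) and Il33 (−4.97, SE 0.167) fell too. In all, 8687 of 14983 genes passed, 4327 higher and 4360 lower and 2955 at least 2-fold, after 8003 at 24 h and 8061 at 48 h. Library totals alone put the all-gene medians at −0.134, −0.158 and −0.177 at 24, 48 and 72 h, in place of −0.0141, −0.017 and −0.0192, and lowered the shares of higher genes from 50.4% to 37.3%, from 50.5% to 35.4% and from 49.8% to 35.9%.

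The lists in these cells at 72 h showed actin and SRF targets higher in all 22 (median 1.61, camera adjusted p = 6.74e-16), mesenchymal markers higher in 18 of 22 and lower in 2 (1.78e-10), matrix genes higher in 26 of 37 and lower in 7 (3.66e-08) and TGFβ and SMAD targets higher in 23 of 31 and lower in 5 (2.75e-07). Epithelial genes fell in 21 of 30 and rose in 6 (2.53e-05), with the simple epithelial keratin Krt19 at −3.47 (SE 0.192). All 28 G2/M genes fell (median −0.99, 6.74e-16), with Kif23 at −1.50 (SE 0.0611), and 29 of 30 replication genes fell (4.77e-16), with Uhrf1 at −1.76 (SE 0.0639). NRF2 targets fell in 19 of 23 and rose in 3 (1.72e-05), among them Gclc (−2.66, SE 0.066). These lists also passed with an estimated correlation, and their counts were the same adjusted over the list alone. Cholesterol synthesis genes did not pass here, with 9 lower (10 adjusted over the list alone) and 5 higher of 24 (0.342).

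Before TGFβ1, the libraries labelled ATF3 knockdown differed from control in genes that TGFβ1 regulates, although Atf3 itself was not lower there. Fn1 stood at 2566 CPM (SD 152) against 1326 CPM (SD 8.68; log2 fold change 0.95, SE 0.0529, adjusted p = 6.73e-14), Zeb1 at 73.8 CPM (SD 9.76) against 40.0 CPM (SD 2.31; 0.88, SE 0.0773) and Snai2 at 9.21 CPM (SD 0.765) against 3.05 CPM (SD 0.575; 1.59, SE 0.16). The chromatin factor Hmga2 (1.48, SE 0.0562), the receptor Fgfr1 (2.64, SE 0.1), the secreted glycoprotein Angptl2 (3.43, SE 0.144) and the peptide hormone gene Uts2b (4.13, SE 0.19) were higher. Lower were tubulin Tubb2a (−2.50, SE 0.139), the endoplasmic reticulum gene Ei24 (−2.21, SE 0.0854), the Notch target Hey1 (−2.15, SE 0.243) and laminin Lamb3 (−1.39, SE 0.0537). Cdh1 gave 0.15 (adjusted p = 0.0916, or 0.0389 with only the groups compared, 0.0272 without a filter on low counts, and 0.21 and 0.029 without replicate 2 of the libraries labelled ATF3 knockdown) and Acta2, near 0 in both groups, −1.21 (adjusted p = 0.159, or −2.66 and 0.031 without replicate 2 of the libraries labelled ATF3 knockdown). In all, 5550 genes passed, 2794 higher and 2756 lower, and 778 at least 2-fold. Replicate 1 of these libraries stood farther from replicates 2 and 3 (chi-square per degree of freedom 10.6 and 10.9) than those did from each other (3.86), and 4745 genes passed without it.

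Of the actin and SRF targets 16 of 22 were higher and 0 lower at 0 h (median 0.58, camera adjusted p = 1.75e-11), with zyxin (Zyx, 1.43, SE 0.044), Cnn2 (1.33, SE 0.0511) and Pdlim7 (0.96, SE 0.0634) as examples. Cholesterol synthesis genes were lower in 22 of 24 (median −0.69, adjusted p = 4.77e-16), among them Idi1 (−1.29, SE 0.0988) and Sqle (−1.08, SE 0.0641). G2/M genes were lower in 23 of 28 (24 adjusted over the list alone; 4.16e-11) and replication genes in 25 of 30 (27 adjusted over the list alone; 7.26e-13), with Ccna2 at −0.84 (SE 0.0664) and Ccne1 at −1.38 (SE 0.111). Inflammatory genes were higher in 14 of 27 (16 adjusted over the list alone) and lower in 3 (0.000242), among them Ccl7 (1.83, SE 0.11), and epithelial genes lower in 18 of 30 and higher in 3 (2.88e-05). These lists passed with an estimated correlation. Hypoxia genes were lower in 27 of 33 and higher in 2 (4.98e-11; adjusted p = 0.0671 with an estimated correlation), with Aldoc at −2.18 (SE 0.311). EMT transcription factors were higher in 7 of 11 and lower in 1 (0.00152; adjusted p = 0.0714 with an estimated correlation), and both counts were the same adjusted over the list alone. The 200 genes that TGFβ1 induced in controls of experiment 1 were higher in 157 and lower in 15 (median 0.52), and the 200 repressed genes lower in 159 and higher in 5 (median −0.41).

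At 72 h the libraries labelled ATF3 knockdown had more Acta2, 130 CPM (SD 1.08) against 26.4 CPM (SD 3.01; log2 fold change 2.30, SE 0.09, adjusted p = 9.64e-17), and more Cdh1, 196 CPM (SD 24.7) against 108 CPM (SD 6.78; 0.86, SE 0.072). The actin bundling gene Lcp1 (4.23, SE 0.181), skeletal actin Acta1 (3.20, SE 0.0996), Notch1 (3.04, SE 0.196) and Col1a1 (1.36, SE 0.107) were higher. The cornified envelope gene Sprr1a (−4.08, SE 0.137), the prolyl hydroxylase Egln3 (−3.32, SE 0.269), the EGF family ligand Areg (−2.27, SE 0.15) and Vim (−0.67, SE 0.0448) were lower, with a smaller difference of Fn1 (−0.20, SE 0.0524) that did not pass with only the groups compared (−0.21, adjusted p = 0.0767). Zeb1 (0.07, adjusted p = 0.512) and Snai1 (0.13, adjusted p = 0.27) did not pass. The genes that passed numbered 4577, 2334 higher and 2243 lower and 670 at least 2-fold, and they numbered 4760 at 24 h and 3835 at 48 h. At 24 h 47.7% of them were higher, or 37.7% with library totals alone. Replicate 2 of the libraries labelled ATF3 knockdown at 72 h stood apart from replicates 1 and 3 (chi-square per degree of freedom 19.2 and 17.6, against 5.70 between those and a median of 5.29 over the pairs of experiment 2), and in control replicates 2 and 3 gave 14.55. Without that knockdown library 4231 genes passed, 662 of them at least 2-fold, and without control replicate 2 or 3 there were 3895 or 4266.

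Interferon response genes were higher in these libraries at 72 h in 15 of 29 and lower in 0 (17 higher, adjusted over the list alone; median 0.53, camera adjusted p = 1.04e-06), with the GTPase gene Gbp3 at 3.79 (SE 0.759) and Ifit1, at 52 against 2 counts, at a ratio of 27 (95% counting interval 7.11 to 229). In tests of this list added after its levels were seen, it was higher in 10 and lower in 1 at 0 h (median 0.29; adjusted p = 0.00749 with an estimated correlation). At 24 h it did not pass, with 1 higher and 4 lower (median −0.15; adjusted p = 0.395 with an estimated correlation), and the 24 h interaction was lower in 10 and higher in 0 (11 lower, adjusted over the list alone; median −0.49; adjusted p = 0.00107 with an estimated correlation). Against control at 48 h the list was higher in 9 and lower in 0 (10 higher, adjusted over the list alone; median 0.51; adjusted p = 0.000753 with an estimated correlation). The 48 h interaction did not pass (3 higher and 2 lower, or 4 and 2 adjusted over the list alone; median 0.17; adjusted p = 0.585 with an estimated correlation). That at 72 h passed the other way from that at 24 h, with 8 higher and 2 lower (median 0.13; adjusted p = 0.0403 with an estimated correlation). Its medians per library at 24 h were −0.53 to −0.346 in these libraries and −0.395 to −0.0645 in control. Inflammatory genes were higher in 15 of 27 and lower in 4 (5 adjusted over the list alone; 6.18e-05), among them Ccl20 (2.13, SE 0.146) and Vcam1 (1.86, SE 0.112). Hypoxia genes were lower in 26 of 33 (28 adjusted over the list alone) and higher in 1 (median −0.69, 1.38e-20), with Egln3 and Bnip3 (−2.27, SE 0.198) among them. Cholesterol synthesis genes were lower in 21 of 24 (median −0.61, 4.78e-17), G2/M genes in all 28 (median −0.47, 4.3e-16) and luminal markers in 6 of 9 (median −0.83, 3.23e-05). ATF4 and stress response genes were lower in 19 of 30 (21 adjusted over the list alone) and higher in 2 (2.36e-08). All of these passed with an estimated correlation. AP-1 genes were lower in 12 of 26 and higher in 2 (14 and 4 adjusted over the list alone; 0.0107; adjusted p = 0.151 with an estimated correlation).

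The interaction at 72 h, from which the difference at 0 h is subtracted, was lower for several genes named above as higher at 0 h. Fn1 gave −1.15 (SE 0.0744, adjusted p = 7.73e-12), Zeb1 −0.81 (SE 0.106), Snai2 −0.95 (SE 0.22), Hmga2 −1.17 (SE 0.0787), Fgfr1 −2.52 (SE 0.123) and Angptl2 −3.33 (SE 0.163). Fgfr1 ended at 136 CPM (SD 8.93) against 125 CPM (SD 6.57), and Angptl2 at 155 CPM (SD 8.9) against 144.5 CPM (SD 2.7). Snai1 (−0.88, SE 0.165), collagen V (Col5a3, −4.96, SE 0.353) and the cytokine Il11 (−2.47, SE 0.145) rose less, and Notch1 (3.45, SE 0.24), the exchange factor gene Arhgef26 (3.16, SE 0.239) and Id1 (1.48, SE 0.144) responded more upwards. Cdh1 fell less (0.71, SE 0.0993, adjusted p = 7.29e-06). Acta2 rose more (3.51, SE 0.644, adjusted p = 0.000275), a value that rests on 0.0801 CPM (SD 0.0986) against 0.211 CPM (SD 0.12) at 0 h. The interaction passed for 1927 genes, 849 higher and 1078 lower, after 2797 at 24 h and 1742 at 48 h, and for 2237 at 72 h without replicate 2 of the libraries labelled ATF3 knockdown at 72 h. At 24 h the share of higher genes was 41.5%, or 28.8% with library totals alone. The response within these libraries passed for 8145 genes, 51.1% higher, or 35.8% with library totals alone, with an all-gene median of −0.16 in place of −0.00428.

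Actin and SRF targets were lower in this interaction in 16 of 22 and higher in 1 (median −0.52, camera adjusted p = 1.05e-17), with Zyx at −1.23 (SE 0.0607) and Cnn2 at −1.10 (SE 0.0705). This list stood higher in these libraries at 0 h, a difference that the interaction subtracts. Its value here is therefore not a lower level at 72 h. EMT transcription factors were lower in 7 of 11 and higher in 0 (1 adjusted over the list alone; median −0.64, 9.98e-06), mesenchymal markers lower in 8 of 22 and higher in 2 (10 and 3 adjusted over the list alone; 3.91e-06) and matrix genes lower in 13 of 37 and higher in 2 (15 and 3 adjusted over the list alone; 3.32e-06). AP-1 genes were lower in 9 of 26 and higher in 1 (13 lower, adjusted over the list alone; 9.98e-06), with Jun at −1.60 (SE 0.0844) and Fosl1 at −1.52 (SE 0.123). Epithelial genes were higher in 10 of 30 and lower in 2 (13 and 3 adjusted over the list alone; median 0.32, 1.86e-05). These lists passed with an estimated correlation, whereas hypoxia genes, lower in 13 of 33 (15 adjusted over the list alone; 1.84e-05), did not (adjusted p = 0.221 with an estimated correlation). The induced list taken from experiment 1 gave a median of −0.49, with 141 lower and 9 higher (7.87e-62), and the repressed list 0.15, with 59 higher and 11 lower (1.22e-08). At 72 h itself the induced genes did not differ past the test (median 0.04, 78 higher and 63 lower, adjusted p = 0.519). The repressed genes still did, with 104 lower and 26 higher (median −0.27; adjusted p = 0.00122 with an estimated correlation).

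In 4T1 carcinoma cells the question was whether a PBRM1 knockdown alters gene expression with and without 4 d of TGFβ1. Control cells after 4 d had 480 CPM (SD 41.8) of the collagenase Mmp13 (ENSMUSG00000050578, chromosome 9, 7272514 to 7283331) against 1.05 CPM (SD 0.0524) at 0 d (log2 fold change 8.83, SE 0.103, adjusted p = 7.19e-37). The siderophore-binding protein Lcn2 rose from 2.38 CPM (SD 0.366) to 324 CPM (SD 15; 7.08, SE 0.0826). The nitric oxide synthase Nos2 (6.21, SE 0.11), Csf2 (5.45, SE 0.172), Mmp9 (5.14, SE 0.0445), the matricellular gene Postn (4.39, SE 0.0896) and C3 (4.03, SE 0.0544) rose too. The KIT ligand gene Kitl (−3.44, SE 0.0899), the peptidase Klk10 (−4.14, SE 0.111) and Nrp1 (−2.21, SE 0.051) fell. The EMT genes gave Fn1 at 1.30 (SE 0.0197), Snai1 at 0.55 (SE 0.0609), Vim at 0.08 (SE 0.0225, adjusted p = 0.00112, or 0.05 and 0.0952 without a filter on low counts) and Cdh1 at −0.41 (SE 0.0244). Epcam rose by 0.47 (SE 0.0338). In all, 10316 of 13854 genes passed, 5412 higher and 4904 lower, and 2285 at least 2-fold, 1630 of them higher. The labels call the untreated groups 0 h, while the protocol speaks of seeding with or without TGFβ1, so it stays open whether untreated cells were cultured equally long and whether time in culture is separated from TGFβ1.

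All 39 interferon response genes rose (median 1.90, camera adjusted p = 1.67e-11; adjusted p = 0.267 with an estimated correlation), with Zbp1 at 5.29 (SE 0.154) and Ifi44 at 5.12 (SE 0.165). Inflammatory genes rose in 26 of 28 and fell in 1 (median 2.13, 1.52e-09; adjusted p = 0.214 with an estimated correlation), and MHC class I genes rose in 17 of 19 and fell in 2 (9.03e-07; adjusted p = 0.221 with an estimated correlation), with Psmb9 at 2.67 (SE 0.0939) and H2-T23 at 2.47 (SE 0.0789). Matrix genes rose in 31 of 37 and fell in 3 (8.19e-09; adjusted p = 0.214 with an estimated correlation), and hypoxia genes rose in 27 of 34 and fell in 6 (1.38e-06; adjusted p = 0.369 with an estimated correlation). Cholesterol synthesis genes fell in 20 of 24 and rose in 3 (1.21e-05; adjusted p = 0.214 with an estimated correlation). Replication genes fell in 28 of 30 (4.3e-10; adjusted p = 0.221 with an estimated correlation), with Rrm2 at −1.47 (SE 0.0469). The counts were the same adjusted over the list alone. Of the 12 leukocyte markers listed, 11 stayed below 1 CPM at 4 d in control, with Csf1r at 0.549 CPM (SD 0.135) as the next below Cd68, a lysosomal glycoprotein gene, which stood at 16.8 CPM (SD 1.25) after 5.29 CPM (SD 0.397) at 0 d.

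Without TGFβ1, the 4T1 knockdown lowered the cytokine Il1a (log2 fold change −2.94, SE 0.0811, adjusted p = 6.87e-25) and C3 from 28.3 CPM (SD 3.47) to 4.37 CPM (SD 0.0476; −2.69, SE 0.0993). The septin-binding protein gene Cdc42ep5 (−4.39, SE 0.177), the FGF carrier Fgfbp1 (−2.29, SE 0.0484), the chemokine Cxcl5 (−2.26, SE 0.121) and the cystine transporter Slc7a11 (−2.18, SE 0.0923) were lower. Higher were Scara5 (3.28, SE 0.129), the sulfatase Sulf2 (2.76, SE 0.124), the activin subunit Inhbb (2.64, SE 0.113), the integrin Itga1 (2.41, SE 0.0763), Egr1 (2.32, SE 0.1) and Cyp1b1 (1.98, SE 0.114). Cdh1 (−0.15, SE 0.0243), Fn1 (−0.12, SE 0.0194) and Vim (0.33, SE 0.0225) differed little. In all, 7072 genes passed, 3816 higher and 3256 lower, and 604 at least 2-fold. Among those passing, 54.0% were higher, or 65.4% with library totals alone.

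Integrated stress response genes were lower in 28 of 30 at 0 d (median −0.60, camera adjusted p = 1.46e-19; adjusted p = 0.099 with an estimated correlation), with Chac1 at −1.70 (SE 0.0766) and Trib3 at −1.42 (SE 0.0604). Hypoxia genes were lower in 30 of 34 and higher in 2 (median −0.56, 7.24e-20; adjusted p = 0.214 with an estimated correlation), among them Car9 (−1.39, SE 0.0853) and Bnip3 (−1.37, SE 0.0467). Inflammatory genes were lower in 17 of 28 and higher in 3 (1.34e-06; adjusted p = 0.241 with an estimated correlation). AP-1 genes were higher in 16 of 26 and lower in 6 (0.00269; adjusted p = 0.29 with an estimated correlation). Adjusted over the list alone these counts were the same.

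After 4 d the knockdown cells had 11.98 CPM (SD 2.5) of Lcn2 against 324 CPM (SD 15) in control (log2 fold change −4.79, SE 0.0625, adjusted p = 1.4e-34), and 52.1 CPM (SD 7.57) of Mmp13 against 480 CPM (SD 41.8; −3.21, SE 0.0571). The transcription factor genes Ehf (−4.48, SE 0.152) and Pou2f2 (−4.30, SE 0.185), C3 (−3.68, SE 0.0521) and Postn (−2.68, SE 0.072) were lower. Kitl (2.22, SE 0.103), Fgfr1 (2.16, SE 0.0992) and Inhbb (1.60, SE 0.0819) were higher. Fn1 (−0.25, SE 0.0193) was lower, and Cdh1 was at 466 CPM (SD 4.67) against 465 CPM (SD 11.3; 0.00, adjusted p = 0.936, or 0.06 and 0.0311 with library totals alone). In all, 7643 genes passed, 3857 higher and 3786 lower, and of 710 at least 2-fold 464 were lower. Among those passing 50.5% were higher, or 61.6% with library totals alone.

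Interferon genes were lower in knockdown at 4 d in 35 of 39 (median −0.96, camera adjusted p = 2.02e-13; adjusted p = 0.221 with an estimated correlation), with Ifi44 at −2.52 (SE 0.115). Inflammatory genes were lower in 26 of 28 and higher in 1 (median −1.15, 5.58e-16; adjusted p = 0.191 with an estimated correlation), and MHC class I genes lower in 14 of 19 and higher in 1 (9.03e-07; adjusted p = 0.221 with an estimated correlation), with the MHC class I transactivator Nlrc5 at −2.40 (SE 0.0657), H2-D1 at −1.24 (SE 0.0294) and B2m at −0.94 (SE 0.0277). Cholesterol synthesis genes were higher in 22 of 24 and lower in 1 (median 0.81, 1.46e-19; adjusted p = 0.0567 with an estimated correlation), among them Hmgcs1 (1.29, SE 0.0309). Counts adjusted over the list alone were the same.

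The interaction in 4T1, the 4 d response in knockdown minus that in control, was positive for the cholesterol genes Mvd (1.42, SE 0.0948), Hmgcs1 (1.34, SE 0.0437, adjusted p = 2.65e-22) and Idi1 (1.29, SE 0.0668). It was negative for the stromelysins Mmp3 (−2.97, SE 0.0912) and Mmp10 (−2.17, SE 0.116), the protease inhibitor Slpi (−2.62, SE 0.197), ceruloplasmin (Cp, −2.01, SE 0.0569) and Csf3 (−1.80, SE 0.0691). Cdh1 gave 0.15 (SE 0.0345), Fn1 −0.13 (SE 0.0274), and Snai1 −0.02 (adjusted p = 0.905). The interaction passed for 3918 genes, 1830 higher and 2088 lower, and of 301 beyond 2-fold 242 were lower. The share of higher genes, 46.7%, was 53.8% with RLE factors, 54.2% with DESeq2 and 56.0% without a filter on low counts. Cholesterol synthesis genes were higher in 23 of 24 (median 1.01, camera adjusted p = 1.42e-42), and passed with an estimated correlation too (adjusted p = 0.00774). Interferon genes were lower in 26 of 39 (29 adjusted over the list alone) and higher in 1 (median −0.86, 1.52e-09; adjusted p = 0.29 with an estimated correlation), with Oas3 at −1.37 (SE 0.191) and Zbp1 at −1.71 (SE 0.354). Inflammatory genes were lower in 14 of 28 and higher in 5 (median −0.37, 0.00114; adjusted p = 0.354 with an estimated correlation), with the same counts adjusted over the list alone. Hypoxia genes were higher in 25 of 34 and lower in 2 (26 and 3 adjusted over the list alone; 1.34e-15; adjusted p = 0.221 with an estimated correlation), and stress response genes higher in 21 of 30 (23 adjusted over the list alone) and lower in 1 (7.5e-12; adjusted p = 0.191 with an estimated correlation). The TGFβ-induced list taken from NMuMG controls of experiment 2 gave −0.12, with 81 of 189 lower and 34 higher (8.59e-05; adjusted p = 0.353 with an estimated correlation), and the repressed list gave 0.00 (adjusted p = 0.916).

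**Figure D3:**
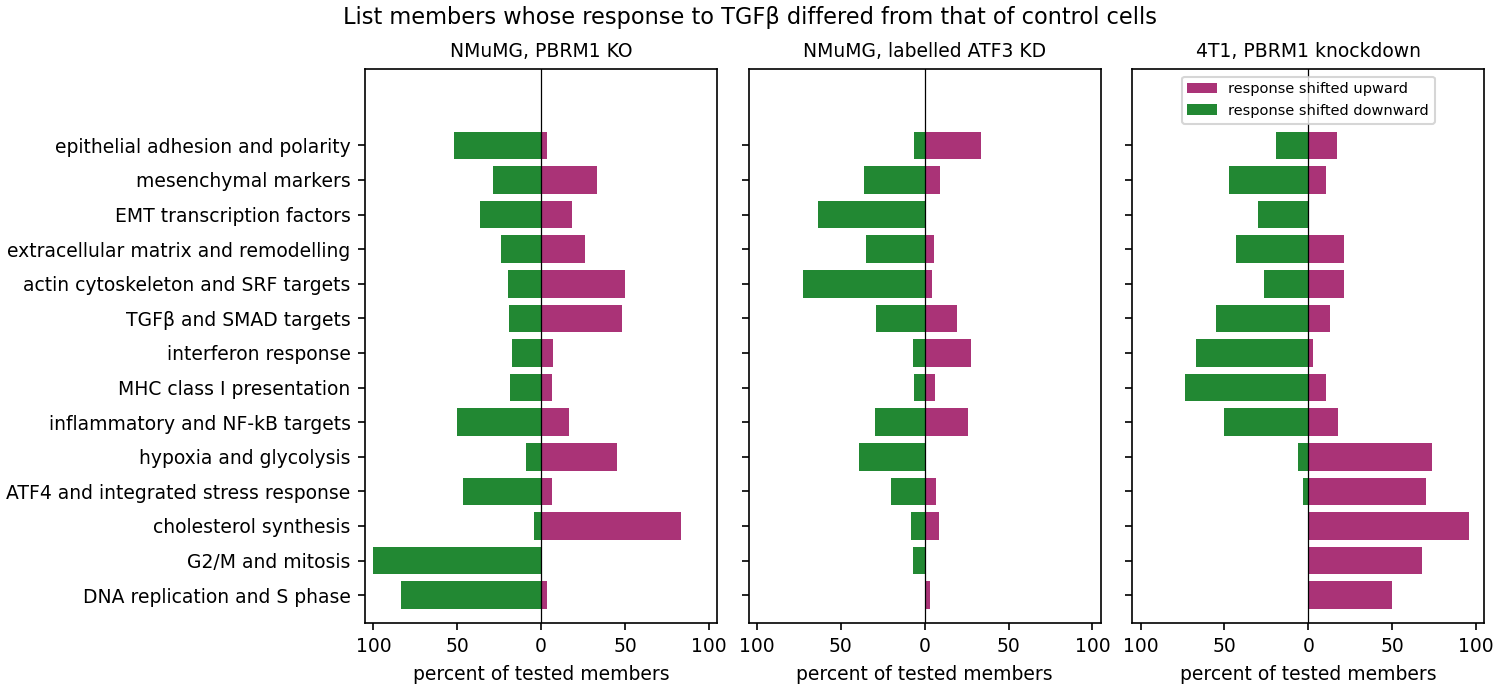
Share of the tested members of 14 gene lists (horizontal axis, percent) whose response to TGFβ1 was shifted upward (bars to the right) or downward (bars to the left) past the interaction test, at 72 h in experiments 1 and 2 and at 4 d in experiment 3. Downward shifts cover all 28 G2/M genes in experiment 1 and 16 of 22 actin and SRF targets in experiment 2, and upward shifts 23 of 24 cholesterol synthesis genes in experiment 3.

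**Figure D4:**
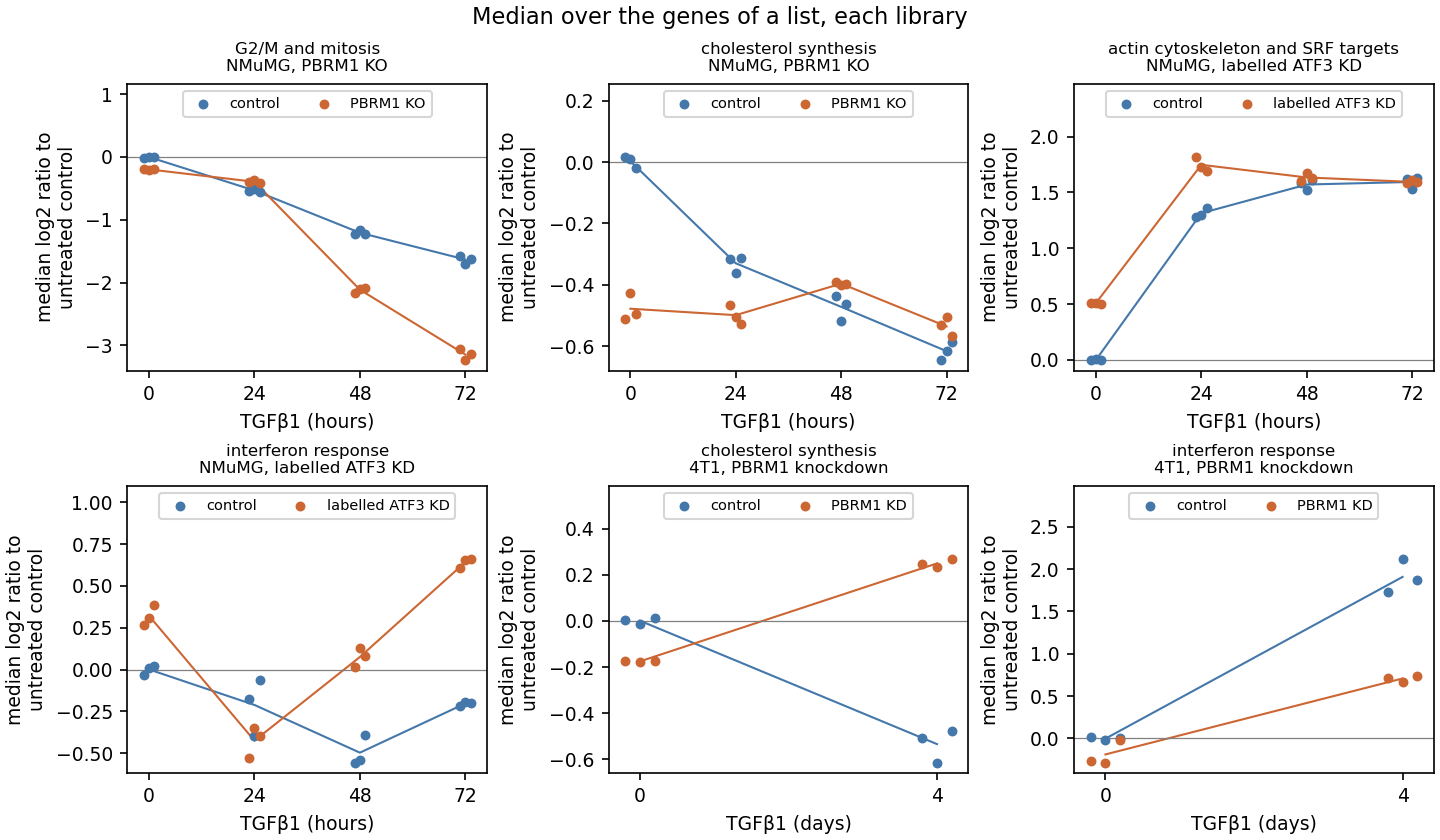
Median over the genes of a list of the log2 ratio to untreated control (vertical axis) by time of TGFβ1, with each point a library and lines through the means of n = 3, for G2/M and cholesterol synthesis genes in experiment 1, actin and interferon genes in experiment 2 and cholesterol synthesis and interferon genes in experiment 3. The G2/M and mitosis list at 72 h lies between −1.57 and −1.70 in the control libraries and between −3.06 and −3.24 in the PBRM1 knockout libraries.

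The experiments were compared by the overlap of genes that passed the same way, in comparisons that share no library. At 0 h, 2380 genes passed the same way in PBRM1 knockout and in the libraries labelled ATF3 knockdown, where 1250 were expected from independent lists over 13965 genes, and 857 passed in opposite ways (1250 expected). Of those at least 2-fold in both, 131 went the same way (16.4 expected) and 21 opposite (16.6 expected). At 72 h the overlap was 1668 (1134 expected) with 1199 opposite (1134 expected), and at 2-fold 77 went the same way (21.65 expected) and 82 opposite (23.4 expected). At 0 h in NMuMG knockout and 0 d in 4T1 knockdown, 2076 of 12331 genes passed the same way (1561 expected) and 1537 opposite (1571 expected). At least 2-fold in both, 55 went the same way (7.25 expected), such as Col6a2 (1.86 and 3.87), Fgfr1 (2.12 and 3.37), Cyp1b1 (3.21 and 1.98), Cxcl16 (−3.38 and −1.21) and Fgfbp1 (−4.08 and −2.29), and 20 opposite (7.31 expected).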

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

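The tests of leukocyte markers, of days in culture, of a difference between cell populations, of the G2/M list at 24 and 48 h and of the difference that splits carry were chosen only after the results were seen.

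The interaction test of the TGFβ1 response between genotypes passed for many genes and lists, among them the TGFβ-repressed list in experiment 1 (median −0.49). Of the values that passed, 10 others were taken for a closer look. In PBRM1 knockout at 72 h these were Atf3 (−1.15 on the log2 scale), the medians of the G2/M list (−1.28) and the cholesterol synthesis list (0.56), and the median of the TGFβ-induced list (0.101; adjusted p = 0.0532 with an estimated correlation). In the libraries labelled ATF3 knockdown at 72 h they were Cdh1 (0.71), Acta2 (3.51), actin and SRF targets (median −0.524) and the TGFβ-induced list (median −0.494). Both of these lists stood higher in these libraries at 0 h, which the interaction subtracts. In 4T1 with PBRM1 knockdown at 4 d they were cholesterol synthesis (median 1.01) and interferon response (median −0.862; adjusted p = 0.29 with an estimated correlation).

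The first pattern is the state of the libraries labelled ATF3 knockdown at 0 h, where the TGFβ-induced list stood at a median of 0.52 above control. An exchange of labels between the groups at 0 h is argued against by the genes that differed at least 2-fold the same way at 24, 48 and 72 h, of which 85.6% (119 of 139) had that same sign at 0 h. Matched lists of like gene length and expression reached at most 0.0822, and with library totals alone the median was 0.531. A difference between the cell populations other than ATF3 cannot be told apart from an effect of the shRNA, since Atf3 mRNA at 0 h was 0.309 above control (log2, adjusted p = 0.106) and each genotype is 1 population as far as the labels tell. A candidate explanation is a partial TGFβ-like state of this population before treatment, which stays open together with an earlier fall of ATF3. The shift is not particular to these libraries. In PBRM1 knockout at 0 h the induced list taken from experiment 2 had a median of 0.21 (106 higher and 43 lower). The repressed list had −0.11 (107 lower and 45 higher), with adjusted p = 0.0998 and 0.0003 with an estimated correlation.

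The second pattern is the further fall of G2/M genes in PBRM1 knockout at 72 h. Matched lists of like length and expression went no lower than −0.175 against −1.28 for the G2/M list, and library totals alone gave −1.35, which argues against both biases as the whole cause. The pattern holds for later times only, with a median of −0.79 at 48 h, while at 24 h the list fell less in knockout (0.37, 27 of 28 genes). The tables are consistent with less cycling of the knockout cells at 48 and 72 h of TGFβ1 (−1.28 at 72 h) and not at 24 h, and a difference in density of the cultures stays open, since it was not tested.

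The third pattern is the rise of interferon and inflammatory genes after 4 d in 4T1 and their lower response in knockdown, although against other genes neither list passed with an estimated correlation (adjusted p = 0.267 and 0.214 for the rise, 0.29 and 0.354 for the interaction) and the inflammatory list was already lower at 0 d in 17 of 28. Leukocytes in the cultures are argued against by 0 of 6 markers at 1 CPM or more, chosen from a list of 12 of which Cd68 alone exceeded it (16.8 CPM, and 5.29 CPM at 0 d). A single library is argued against by the 22 of 27 interferon genes that still passed the same way without any 1 library, at the lowest. Days in culture in place of TGFβ1 cannot be told apart from it, since 0 groups are labelled 4 d without TGFβ1 and the labels leave open how long untreated cells were cultured.

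Other splits of the libraries were tried for each comparison of 2 groups. Each has only 10 splits of its 6 libraries, too few for a share under 0.05, and 1 of 10 (the real one) reached the real count. Fits of those 6 libraries gave for TGFβ1 in experiment 1 8370, 9189 and 9599 genes at 24, 48 and 72 h in control and 9778 at 72 h in knockout, and for knockout 6500, 6742, 6935 and 6800 at 0, 24, 48 and 72 h. In experiment 2 they gave 8205, 8473 and 8310 in control, 6948 in the libraries labelled ATF3 knockdown, and 5684, 5021, 4690 and 3064 between genotypes. In experiment 3 they gave 10201 and 9500 for TGFβ1 and 7361 and 7235 for knockdown at 0 and 4 d. The highest of the other splits called 0 genes, except 1 gene for knockout at 48 h.

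For interactions, 100 splits were drawn. Splits as large, with the real one among them, numbered 1 for experiment 1 at 24 h (2766 genes, highest other 2204), 1 at 48 h (3462, highest other 3069) and 2 at 72 h (3810, highest other 7876). In experiment 2 they numbered 2 at 24 h (3085, highest other 6504) and 4 at 72 h (1451, highest other 5871), and in experiment 3 they numbered 2 (3918, highest other 8531). These shares do not exclude chance. Splits that mix the genotypes at a time put their difference into the spread, which can lower the count with or without an interaction. Every other split as large kept or exchanged the genotypes in full at a time. In 4 of the 7 interactions the split with the highest count exchanged the genotypes in full at 1 time and called at least 2 times the real count, which points to the difference between genotypes as a structure of the samples. Such a split was not among those drawn for the other 3. For experiment 2 at 48 h (6 splits, 2182 genes, highest other 2657) the splits decide nothing either, since all 5 other splits as large kept or exchanged the genotypes in full at 1 time and so carry their difference. Nor do they for 5 of the TGFβ lists, where the carried difference alone, computed from the genotype comparisons, reaches the real median in 7 or more of the 100 splits. In experiment 1 the induced list (0.101, highest other 0.53) was reached in 53 splits, with 55 from the carried difference, and the repressed list (−0.491, highest other 0.784) in 13, with 13. The latter gave adjusted p = 8.37e-08 with an estimated correlation and medians of −0.525 to −0.484 without 1 library. In experiment 2 the induced list (−0.52, highest other 0.595) was reached in 8 splits, with 7, and the repressed list (0.123, highest other 0.699) in 68, with 68. In experiment 3 the repressed list (0.00472, highest other 0.102) was reached in 83, with 54. The induced list there (−0.121, highest other 0.132) was reached in 3 splits, with 1 from the carried difference. The other splits as large kept or exchanged the genotypes in full at a time, so chance is not excluded for it. That list did not pass against other genes with an estimated correlation (adjusted p = 0.353). For the 3 overlaps (2492, 1139 and 2195 genes in fits of 6 libraries) 1 of 100 pairs of splits, the real one, was as large and the highest other gave 0. These pairs decide nothing, since the other splits call 0 genes or 1 and cannot overlap in more.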

How the results depend on the processing

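The fits without the 0 h libraries of experiment 2, and with 24 h as the start, were chosen after seeing the data. All 27 counts of genes past the threshold, and the 27 counts at 2-fold, stayed within 1.5 times under RLE factors, library totals alone, no filter, 1 CPM in 3 libraries, DESeq2, only the groups compared and the replicate block. So did the 204 values of each kind from fits that left out 1 library. With only the groups compared, the count for the libraries labelled ATF3 knockdown at 72 h fell from 4577 to 3064 genes. Their 72 h interaction fell from 1927 to 1451. Without 1 library, knockout at 0 h ranged from 5810 to 6038 genes, the libraries labelled ATF3 knockdown at 0 h from 4693 to 5083, and the interactions at the last time from 3639 to 3839, 1664 to 2237 and 3450 to 3929. With the replicate block these interactions called 4077, 1835 and 3928 genes, and 52, 50 and 53 lists passed. The replicate numbers were not taken as pairs, since 0 of 84, 84 and 18 pairs of libraries with the same number in different groups correlated above 0.1 (means 0.00692, −0.00513 and 0.00129), although 19 of 24 libraries of experiment 1 lay closest to their own number, against 7 of 24 and 4 of 12 in the others, a hint from the data and not from the design. The block ended the call of cholesterol genes in knockout at 72 h (adjusted p = 0.0536) and changed no other call reported. With an estimated correlation the TGFβ-induced list no longer passed in the interactions of experiment 1 (0.1013, adjusted p = 0.0532) and experiment 3 (−0.1214, adjusted p = 0.353), and of the lists fixed in advance 22 results passed in experiment 1 and 1 in experiment 3. With fry 81 list results passed in experiment 1, as fry does not set a list against other genes. Of 292 list results, 97 lost their call with an estimated correlation and 77 gained one with fry. Overlaps at 2-fold in both held 131, 77 and 55 genes, fewer by construction. Where a call was lost with an estimated correlation, the cause was not tested. Without the 0 h libraries of experiment 2 the genotype comparisons at 24, 48 and 72 h called 4629, 3719 and 4457 genes, and with 24 h as the start the interaction at 72 h called 1947. A like count need not hold the same genes. Both TGFβ lists kept their sign and call with that start. Between genotypes the induced list had medians of 0.52 at 0 h, 0.17 at 24 h and 0.04 at 72 h. The size of its interaction (−0.49) therefore depends on the 0 h libraries. The depth limits genes near 0 counts, such as Acta2 at 0 h, whose interaction rests on few reads. No reported list or named gene that passed changed its sign under the alternatives run for it. The TGFβ-repressed list in the interaction of experiment 3, which did not pass (0.00472), was at −0.00119 with 1 CPM in 3 libraries, −0.0218 with 100 genes and −0.0192 to 0.0106 without 1 library. The majority of higher or lower genes turned under at least 1 setting in 15 of the 27 comparisons, whose reported shares of higher genes lay between 46.7% and 54.0%. Among all genes, 110 of 10194 passed the opposite way with library totals alone for TGFβ1 at 72 h in knockout and 3 of 9944 in control of experiment 1. Of the named gene values refitted without 1 library, 1793 kept their direction and side of the threshold, 9 lost their call and 4 gained one, and library totals alone ended 1 call and added 4.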

Other observations

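Both hypotheses below come from patterns seen in these data, and their tests were run on the same libraries.

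In 4T1 control cells Atf3 fell after TGFβ1. TGFβ1 for 4 d lowered it in control by −1.25 (log2, SE 0.0982), and less in knockdown (−0.50, SE 0.0949), an interaction of 0.75 (SE 0.138, adjusted p = 7.12e-05). In NMuMG controls of experiment 2 Atf3 rose at 24 h (1.43, SE 0.143) and was back near its start at 72 h (−0.10, adjusted p = 0.599), whereas in experiment 1 it was still 1.39 above its start at 72 h. The difference between these control lines was not tested.

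Shares of abundant transcripts moved with TGFβ1 in NMuMG. The 10 most abundant genes held 4.28% (SD 0.0289) of counts at 0 h in control of experiment 2 and 7.31% (SD 0.355) at 72 h, and genes of ribosomal proteins went from 3.97% (SD 0.115) to 2.9% (SD 0.366). Mitochondrial transcripts stayed between 1.92% and 2.41% in the means of all 20 groups.

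One hypothesis is that the altered TGFβ1 response of PBRM1 knockout runs through the smaller rise of Atf3. Of the 963 genes that passed in both 72 h interactions, 58.9% (567) went the same way in PBRM1 knockout and in the libraries labelled ATF3 knockdown and 396 went opposite ways, where independent lists give 272 and 262. Against control at 72 h, 77 genes at least 2-fold in both went the same way (21.65 expected) and 82 opposite (23.4 expected). The knockout interaction also passed for 2637 genes at 24 h and 3484 at 48 h, when that of Atf3 did not pass. The TGFβ lists, each taken from the other experiment, went opposite ways in these 72 h interactions. The induced list gave 0.10 in knockout (adjusted p = 0.0532 with an estimated correlation) and −0.49 in the libraries labelled ATF3 knockdown, and the repressed list −0.49 and 0.15. In control of experiment 2 Atf3 rose by 24 h (from 9.95 to 26.9 CPM) but was not above its start at 72 h (−0.10, adjusted p = 0.599). In the libraries labelled ATF3 knockdown it stood at 17.8 CPM at 24 h. Their 72 h response of Atf3 was lower too (interaction −0.77, SE 0.221, adjusted p = 0.0182). It went from 12.3 to 6.78 CPM there, while control had no rise to lose at 72 h. The test leaves the hypothesis open, since Atf3 was not lower at 0 h in those libraries and both genotypes carry differences from before TGFβ1. Shared genes may therefore reflect ATF3 or any other difference the populations share.

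Another hypothesis is that genes altered in both PBRM1 experiments respond to PBRM1 itself. Of the 55 genes at least 2-fold the same way without TGFβ1, 60% (33) kept a difference the same way at 24, 48 and 72 h in NMuMG, 42 at 4 d in 4T1 and 27 at all these times. Those include Col6a2, Cyp1b1 and Padi3 among higher genes and Cxcl16 among lower ones. Another 20 genes went opposite ways, where independent lists give 7.31. At 0 h, PBRM1 knockout shared 131 such genes with the libraries labelled ATF3 knockdown (16.4 expected) and 55 with 4T1 knockdown (7.25 expected). The lists differ in length and in the genes tested in both (13965 and 12331), so these counts do not rank the overlaps. The odds ratios for higher and lower genes were 11.8 and 11.8 in the first and 9.5 and 9.93 in the second. Fgfr1, Sdc3, Aif1l and Gm2a belong to both overlaps. A lasting difference between populations predicts the same persistence, so the test does not separate it from PBRM1, and the hypothesis stays open with 1 labelled population per genotype.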
